A study of Mus musculus with 18 samples.

How the data were processed

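Total RNA from mouse B16 F10.9-4 cells was labelled with biotin and hybridized to 18 one-colour Affymetrix arrays. Per the labels' protocols, LIP was switched on by doxycycline in part of the cultures before tunicamycin was added, cDNA was made with the Ambion WT Expression Kit, and fragments were labelled with the Affymetrix WT Terminal Labeling Kit. Samples were grouped from the labels into 6 groups of 3 arrays: vehicle, doxycycline at 0 h, and tunicamycin for 5 or 12 h without or with doxycycline. The replicate numbers are those of 3 independent experiments, so the p-values measure the spread between separate experiments in this cell line.

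The authors deposited log2 intensities for 35557 probe sets. The values were summarised by RMA, and Partek was used, per the submitters' processing notes, which give no version or settings; a genome build is not given in the sources used here. The deposited values were used as they stand. RMA understates the fold change of dim probe sets, since background adds to their signal. Pearson r between arrays of a group lay between 0.993 and 0.998 and 0 pairs of arrays were identical. The group means of the array medians differed by at most 0.05 on the log2 scale. The first 3 principal components held 47.5, 17.4 and 10.1% of the variance. With no detection calls, 1194 olfactory and vomeronasal receptor genes served as a stand-in for silent genes: their median level was 4.75 and their 95th percentile 6.07, and 70.6% of the other genes lay above that percentile.

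Probe sets were joined to genes through the series' own probe table, which covers 23410 of them. Of these 21789 carry 1 gene symbol and 1621 several; 12147 probe sets have no symbol. The Entrez IDs of 21698 of the single-symbol probe sets were found in a mouse gene table, and 0 symbols needed an update. Of the probe sets of 1 gene the one with the highest mean was kept (999 genes had several), which left 19938 genes. Probe sets with several symbols or none were tested apart and are given only as counts and IDs.

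The main test was limma (version 3.58.1, R 4.3.3) on the means of the 6 groups over all 18 arrays, which share 1 estimate of the spread (12 residual degrees of freedom, 5.99 prior degrees of freedom), with Benjamini-Hochberg adjustment per comparison and an adjusted p threshold of 0.05. The 10 comparisons were doxycycline against none at each of the 3 times, tunicamycin for 5 and 12 h against vehicle and against each other, tunicamycin for 5 and 12 h under doxycycline against doxycycline alone, and the doxycycline by tunicamycin interaction at 5 and 12 h. The 26 gene lists were written, and the tests, alternatives and rule for named genes chosen, before the data were examined. Of the lists 25 had at least 5 measured genes and were tested with limma's camera at a preset inter-gene correlation of 0.01; a list of mitochondria-encoded genes had 0 measured. The 568 measured genes on the lists include 11 that are on more than 1 list. Camera with an estimated correlation and the rotation test fry were the alternatives. Counts described as adjusted over the list alone use limma's p-values adjusted among the members of that list.

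The genes named in each comparison were the 6 with the largest rise and the 6 with the largest fall (4 and 4 for the interactions and for the comparisons under doxycycline) among genes past the threshold that moved the same way in all 3 experiments, leaving out predicted and clone-named genes, small RNAs, olfactory and vomeronasal receptors and histone genes (2923 genes); then up to 4 members past the threshold with the largest change from each list described, or the member with the smallest p where 0 passed; and in addition Cebpb, Ddit3, Atf4, Atf3, Trib3, Hspa5, Dnajb9 and Xbp1 in every comparison.

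The replicate numbers pair the arrays because the labels and series design give them as separate experiments. As a check, the deviations from the group means were correlated: over the 45 pairs of arrays with the same number the median r was 0.04 (-0.50 to 0.50), 14 pairs were over 0.1, and over pairs with different numbers the median was -0.01. The main test had no block for the experiment and a fit with that block was an alternative. Other alternatives were a fit of only the compared groups, leaving out the dimmest genes, repeating quantile normalization, setting array medians equal, a variance trend with robust estimation, array weights, the mean of a gene's probe sets, a 2-fold threshold, and leaving out each array and each experiment. After the data were seen 2 more were added: the first principal component of the receptor genes as a covariate, and leaving out the tunicamycin 5 h array of experiment 2 and the tunicamycin 12 h array of experiment 3, which lay at an end of that component.

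The procedure was tested on simulated data with 200 changed genes among 19938. For doxycycline against vehicle it recovered 50.7% of genes changed by 0.3 on the log2 scale and 100% of those changed by 0.6. For the 12 h interaction it recovered 19.4 and 79.1%. The simulated noise was normal and independent between genes, with 1 spread per gene over all arrays and no experiment effect. The rates therefore do not carry over directly to the real comparisons, where more genes changed and the spread differed between arrays. Other software was pandas 2.3.3, matplotlib 3.10.9 and the R package data.table (version 1.17.8).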

Results

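Gene expression was measured on 18 one-colour arrays in mouse B16 F10.9-4 cells, a line derived from the B16 melanoma. In these cells doxycycline switches on LIP, the truncated isoform of the transcription factor C/EBPβ (gene Cebpb), which binds DNA but lacks most of the activating part of the full-length protein. Tunicamycin, an inhibitor of N-linked glycosylation, was added to load the endoplasmic reticulum (ER) with unfolded protein, and cells were taken at 0, 5 and 12 h. The 6 groups were vehicle, doxycycline alone, tunicamycin for 5 h, doxycycline with tunicamycin for 5 h, tunicamycin for 12 h, and doxycycline with tunicamycin for 12 h. Each group held 3 arrays, 1 from each of 3 independent experiments. Values are the authors' log2 intensities after RMA, the number of arrays limits the precision, and changes are given on the log2 scale with their standard error (SE) and limma's adjusted p over 19938 genes. Genes called the largest are the largest among those the rule for named genes admits. A vehicle array at 5 or 12 h and a doxycycline array without the LIP construct were not used here, so time in culture goes with tunicamycin and any effect of doxycycline itself goes with LIP.

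**Figure D1:**
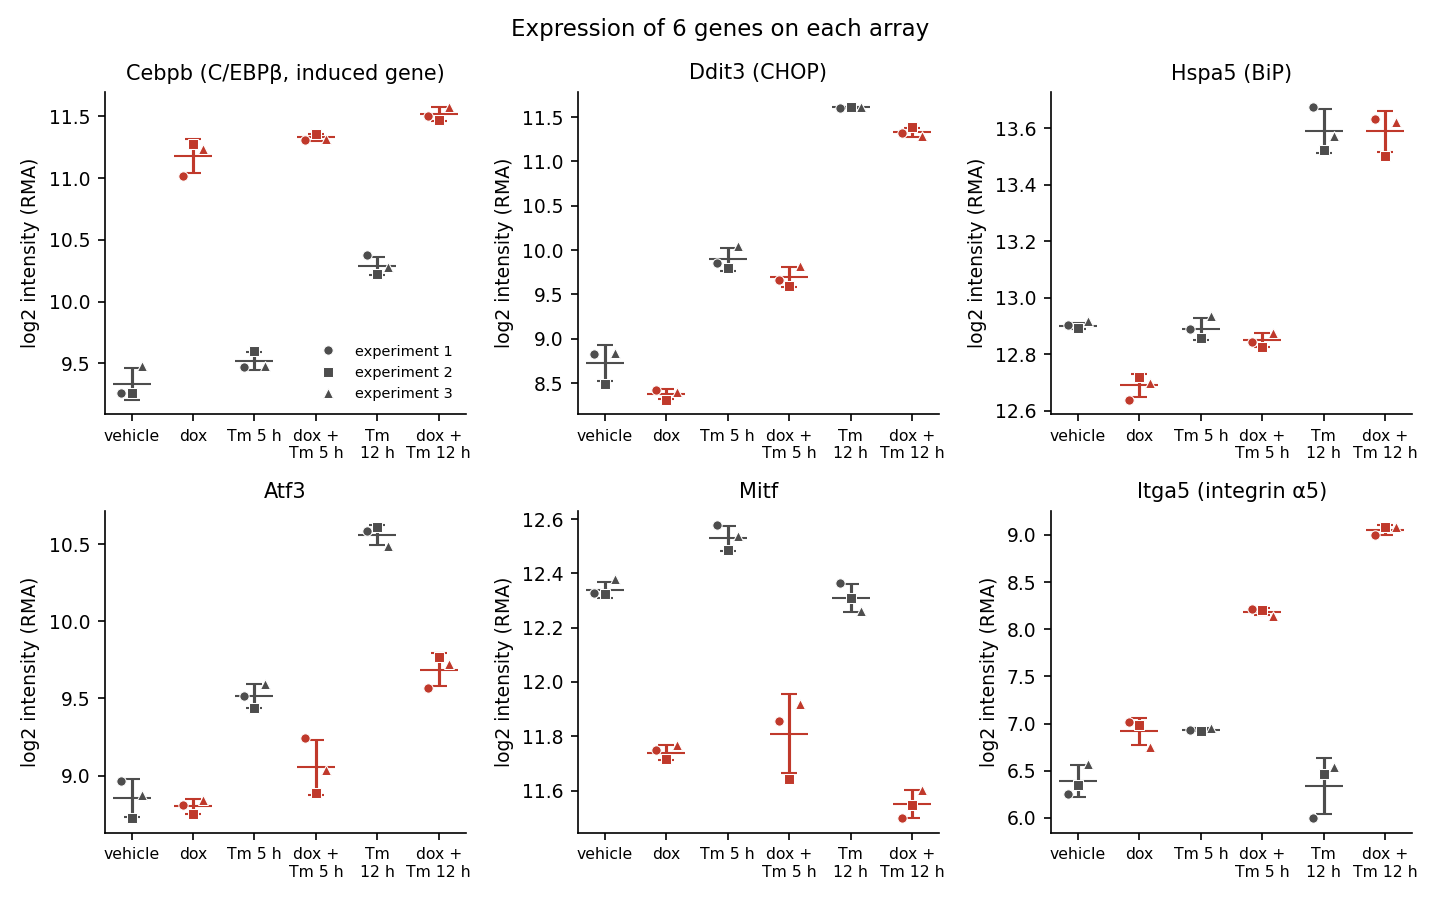
Log2 intensity (RMA) of 6 genes on each array, by treatment group (dox, doxycycline; Tm, tunicamycin). Points are the 3 experiments by symbol, red marks groups with doxycycline, and bars are the mean and SD of 3 arrays; each panel has its own scale. Cebpb stood at a mean of 9.33 in vehicle and 11.18 with doxycycline, and Hspa5 at 13.59 in both 12 h groups.

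Doxycycline before any tunicamycin raised the induced gene and lowered pigment cell genes. Cebpb rose from 9.33 ± 0.126 (SD, n = 3) in vehicle to 11.18 ± 0.137 (SD, n = 3), a change of 1.84 ± 0.071 (SE, adjusted p = 2.02e-11) and a 3.59-fold difference; the probe set reads Cebpb as a whole and does not part LIP from the longer isoforms. Of the 24 measured genes of the melanocyte lineage, 14 fell and 0 rose (17 and 0 adjusted over the list alone), with a list median of -0.32. These included Mitf, the lineage's central transcription factor (-0.60), Mc1r, the receptor for melanocyte-stimulating hormone (-0.95), Gpr143, a melanosome receptor (-0.69), and Rab27a, a GTPase of melanosome transport (-0.61). The list's shift had a camera adjusted p = 4.37e-17, and adjusted p = 0.0117 with an estimated correlation.

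The largest rises after Cebpb were in Cbr2, a carbonyl reductase (1.74), Fstl1, a secreted glycoprotein (1.51), Jam2, a junctional adhesion molecule (1.33), Msrb3, a methionine sulfoxide reductase (1.11), and Cfap100 (1.11). The largest falls were in Syt4, a synaptotagmin (-1.29), Hpgds, a prostaglandin D synthase (-1.19), Nr4a3, an orphan nuclear receptor (-1.15), Dusp4, a MAP kinase phosphatase (-1.04), Bnc2 (-1.01) and Abca12 (-0.99). Genes of G1/S and DNA replication were lower, with 17 of 30 falling and 0 rising (24 and 0 adjusted over the list alone; median -0.19). The replication licensing genes Cdc6 (-0.47), Cdt1 (-0.36), Mcm3 (-0.35) and Mcm4 (-0.32) were among these. The camera adjusted p was 2.36e-15, but adjusted p = 0.0928 with an estimated correlation. ER chaperone, folding and ER-associated degradation (ERAD) genes also stood lower, 14 of 29 falling and 1 rising (17 and 2 adjusted over the list alone; median -0.18, camera adjusted p = 5.57e-09, adjusted p = 0.162 with an estimated correlation). Herpud1 (-0.68), Xbp1 (-0.39), Hyou1 (-0.39), Creld2 (-0.38) and Hspa5, which encodes the chaperone BiP (-0.22, adjusted p = 0.00713), were among the members that fell. Ddit3, which encodes CHOP, fell by 0.35 (adjusted p = 0.0108), Atf4 rose by 0.36 (adjusted p = 0.000618), and Atf3 (-0.05, adjusted p = 0.758), Trib3 (0.09, adjusted p = 0.612) and Dnajb9 (-0.20, adjusted p = 0.116; 0.0239 with array weights) did not pass.

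Matrix and adhesion genes moved in both directions, 6 of 30 rising and 4 falling (7 and 4 adjusted over the list alone; median 0.09, camera adjusted p = 0.00956, adjusted p = 0.321 with an estimated correlation). Thrombospondin Thbs1 (0.80), laminin Lamb1 (0.56) and integrin Itga5 (0.53) rose while integrin Itga4 fell by 0.61. Of 22 interferon-stimulated genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.10, camera adjusted p = 0.0102, adjusted p = 0.0928 with an estimated correlation): the RNA sensors Ddx58 (0.48) and Ifih1 (0.41) and the GTPase Gbp3 (0.32) rose, and the chemokine Cxcl10 fell by 0.30. Of the 21 targets of PERK, ATF4 and CHOP 7 were higher and 3 lower (7 and 4 adjusted over the list alone). Against the other genes this list did not pass (camera adjusted p = 0.157). It passed in fry, which tests the list itself against no change (adjusted p = 0.00238). Cebpb itself is on it, with Atf5 (0.49), Sesn2 (0.40) and Atf4. Amino acid synthesis and transport genes did not pass in camera (adjusted p = 0.143), with 4 higher and 6 lower of 21 (5 and 7 adjusted over the list alone). The transporter Slc1a4 (-0.95) and Aldh18a1 (-0.39) fell and the glycine transporter Slc6a9 (0.61) and Cth (0.38) rose. In all 2135 genes changed, 974 up and 1161 down, 16 of them by at least 2-fold; with array medians set equal the directions were 587 up and 1761 down, and with quantile normalization repeated 1245 up and 1083 down. Of 25 lists tested, 10 passed in camera and 1, the melanocyte list, also with an estimated correlation.

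After 5 h of tunicamycin many targets of PERK, ATF4 and CHOP, part of the ER stress response, had risen while most ER chaperone genes had not. Of the 21 PERK, ATF4 and CHOP targets 11 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.22, camera adjusted p = 2.32e-14, adjusted p = 0.00999 with an estimated correlation). Chac1, a glutathione-degrading enzyme (1.55 ± 0.067), Ddit3 (1.18 ± 0.084, adjusted p = 5.9e-08), the pseudokinase Trib3 (1.16 ± 0.091) and Ppp1r15a, the phosphatase subunit that reverses PERK signalling (0.75 ± 0.066), led this list. Of 29 ER chaperone and ERAD genes 3 rose and 0 fell, over all genes and adjusted over the list alone: Herpud1 (0.80), the co-chaperone Dnajb9 (0.42, adjusted p = 0.00225) and Wfs1 (0.32). Their median was 0.01 (camera adjusted p = 0.475), and Hspa5 stood at -0.01 ± 0.05 (adjusted p = 0.93). The list passed upward with array weights (adjusted p = 0.0398) and without the tunicamycin 5 h array of experiment 2 (adjusted p = 0.0263, median 0.0089).

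Other groups that moved at 5 h were amino acid genes, immediate early genes and mitotic genes. Of 21 amino acid synthesis and transport genes 10 rose (11 adjusted over the list alone; median 0.15, camera adjusted p = 8.1e-09, adjusted p = 0.0809 with an estimated correlation). The cystine transporter Slc7a11 changed by 1.22, Slc1a4 by 0.68, Slc6a9 by 0.48 and Cth by 0.40. Of 27 immediate early and MAPK feedback genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.14, camera adjusted p = 9.21e-06, adjusted p = 0.0728 with an estimated correlation). Maff (0.75), Dusp4 (0.64), Spry4 (0.53) and Fos (0.42) were among these, Maff from a vehicle level of 5.99, below the 6.07 under which 95% of silent receptor genes lay. Mitotic genes fell, 15 of 33 with 0 rising (22 and 0 adjusted over the list alone; median -0.16, camera adjusted p = 7.42e-15, adjusted p = 0.0464 with an estimated correlation). Hmmr (-0.35), Nusap1 (-0.33), Cdc25c (-0.32) and Cenpf (-0.31) were among these. Autophagy genes fell, 6 of 23 with 0 rising (8 lower and 1 higher adjusted over the list alone; median -0.08, camera adjusted p = 1.95e-06, adjusted p = 0.071 with an estimated correlation). Bnip3 (-0.69), Gabarapl1 (-0.38), Wipi1 (-0.37) and Ulk1 (-0.28) were among these. In the C/EBP family Ddit3, Cebpd (0.26) and Cebpg (0.22) rose of 6 measured (4 adjusted over the list alone; camera adjusted p = 0.000389, adjusted p = 0.0275 with an estimated correlation), and Cebpb stood at 0.19 (adjusted p = 0.121). Cebpg lost its call with only the compared groups (0.0919) and with array medians set equal (0.104), and Cebpd with the receptor-gene covariate (0.0736). Of 30 matrix and adhesion genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.13, camera adjusted p = 6.17e-05, adjusted p = 0.105 with an estimated correlation). Ccn2 (1.05), Itga5 (0.54), Thbs1 (0.42) and Ccn1 (0.37) were among these.

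Among all genes the largest rises at 5 h were in Id3 (1.75) and Id1 (1.64), inhibitors of basic helix-loop-helix factors, followed by Chac1, the zinc exporter Slc30a1 (1.36), Slc7a11 and Ddit3. The largest falls were in the zinc importer Slc39a10 (-1.98 ± 0.075, adjusted p = 1.47e-11), Klf12 (-1.10), the phosphodiesterase Pde9a (-0.85), Klhl24 (-0.81), Ccng2 (-0.75) and Eid3 (-0.73). Atf4 rose by 0.36 and Atf3 by 0.66 (adjusted p = 4.16e-05), while Xbp1 stood at 0.13 (adjusted p = 0.239), passing with array weights (0.00805), with the receptor-gene covariate (0.0145) and without the 2 doubted arrays (0.0344). In all 1798 genes changed, 813 up and 985 down, 17 of them by at least 2-fold; with array medians set equal the directions were 495 up and 1578 down, but the larger direction turned to up with quantile normalization repeated (987 up, 920 down), array weights (2247, 2134), the receptor-gene covariate (966, 814) and without the 2 doubted arrays (820, 604). The array of experiment 2 in this group had the largest residual spread of the 18 (SD 0.113 on the log2 scale), and 13 lists passed in camera, 3 of them with an estimated correlation.

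After 12 h of tunicamycin most measured ER folding genes and PERK targets were higher, and cell cycle and sterol genes were lower. Of 29 ER chaperone and ERAD genes 28 rose and 0 fell, over all genes and adjusted over the list alone (median 0.96, camera adjusted p = 5.52e-38, adjusted p = 0.00131 with an estimated correlation). The oxidase Ero1b rose by 2.99 ± 0.094, Herpud1 by 2.29 ± 0.060, Dnajb9 by 2.24 ± 0.079 and Wfs1 by 2.06 ± 0.065. Hspa5, already at 12.90 in vehicle, rose by 0.69 ± 0.050 (adjusted p = 3.81e-09) and Xbp1 by 0.99 (adjusted p = 5.6e-10). Of the 21 PERK, ATF4 and CHOP targets 18 rose and 0 fell, over all genes and adjusted over the list alone (median 1.17, camera adjusted p = 2.22e-26): the stress regulator Nupr1 rose by 3.06 ± 0.087, Ppp1r15a by 2.96 ± 0.066, Trib3 by 2.91 ± 0.091 and Ddit3 by 2.89 ± 0.084.

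Secretory pathway and translocon genes rose in 28 of 32 cases (28 up and 1 down adjusted over the list alone; median 0.39, camera adjusted p = 1.86e-20). The vesicle coat subunit Sec24d changed by 2.03, Arfgap3 by 1.28, the KDEL receptor Kdelr3 by 1.22 and Golgb1 by 0.73. N-glycosylation and hexosamine genes, the pathway whose first step tunicamycin blocks, rose in 21 of 31 cases and fell in 3 (22 and 3 adjusted over the list alone; median 0.28, camera adjusted p = 2.66e-11). The mannosyltransferase Alg12 changed by 1.53, Gnpnat1 by 1.08, Pgm3 by 1.01 and Gfpt1 by 0.94. Amino acid synthesis and transport genes rose in 20 of 21 cases, also adjusted over the list alone (median 0.73, camera adjusted p = 1.51e-24). Slc7a11 (2.73), Slc1a4 (1.98), Slc6a9 (1.77) and Cth (1.76) were among these. Cytosolic aminoacyl-tRNA synthetases rose in 13 of 18 cases, also adjusted over the list alone (median 0.43, camera adjusted p = 4.12e-11). Wars (1.01), Lars (0.94), Tars (0.85) and Cars (0.77) were among these. Cebpb rose by 0.96 (adjusted p = 4.8e-09), Atf4 by 1.07 and Atf3 by 1.71.

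Genes of G1/S and DNA replication fell in 25 of 30 cases (27 adjusted over the list alone; median -0.54, camera adjusted p = 4.83e-19). E2f2 changed by -1.01, Uhrf1 by -0.88 and the cyclins Ccne2 by -0.85 and Ccne1 by -0.83. Mitotic genes fell in 29 of 33 cases, also adjusted over the list alone (median -0.31, camera adjusted p = 2.77e-15). Ccnf (-0.70), Bub1b (-0.62), Cenpf (-0.57) and Kif20b (-0.53) were among these. Cholesterol and fatty acid synthesis genes fell in 21 of 24 cases and rose in 1, also adjusted over the list alone (median -0.39, camera adjusted p = 3.35e-13). The elongase Elovl6 (-0.97), Idi1 (-0.92), Dhcr7 (-0.90) and Stard4 (-0.86) were members that fell. Cytosolic heat shock genes fell in 10 of 14 cases, also adjusted over the list alone (median -0.28, camera adjusted p = 0.000136). Hsph1 changed by -0.92, Dnajb1 by -0.66, Hspb1 by -0.46 and Ahsa1 by -0.39. Apoptosis regulators went both ways, 6 of 27 up and 9 down (7 and 9 adjusted over the list alone), with a median of 0.02 and a camera direction of down (adjusted p = 0.93). The inflammatory caspase Casp4 rose by 2.45, Txnip by 0.77 and Cflar by 0.71, and the BH3-only gene Bcl2l11 fell by 0.68.

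Cyb5r2, a cytochrome b5 reductase (2.83), was also among the 6 largest rises, and the largest falls were in the interferon-inducible GTPase Irgm1 (-1.38), Kank4 (-1.35), Rapgef3 (-1.32), Etv5 (-1.28), Slc39a10 (-1.26) and the transferrin receptor Tfrc (-1.23). In all 5516 genes changed, 2365 up and 3151 down, and 187 by at least 2-fold. Of 14 lists past the camera threshold 11 also passed with an estimated correlation, among them each list described here for 12 h other than the apoptosis regulators.

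**Figure D2:**
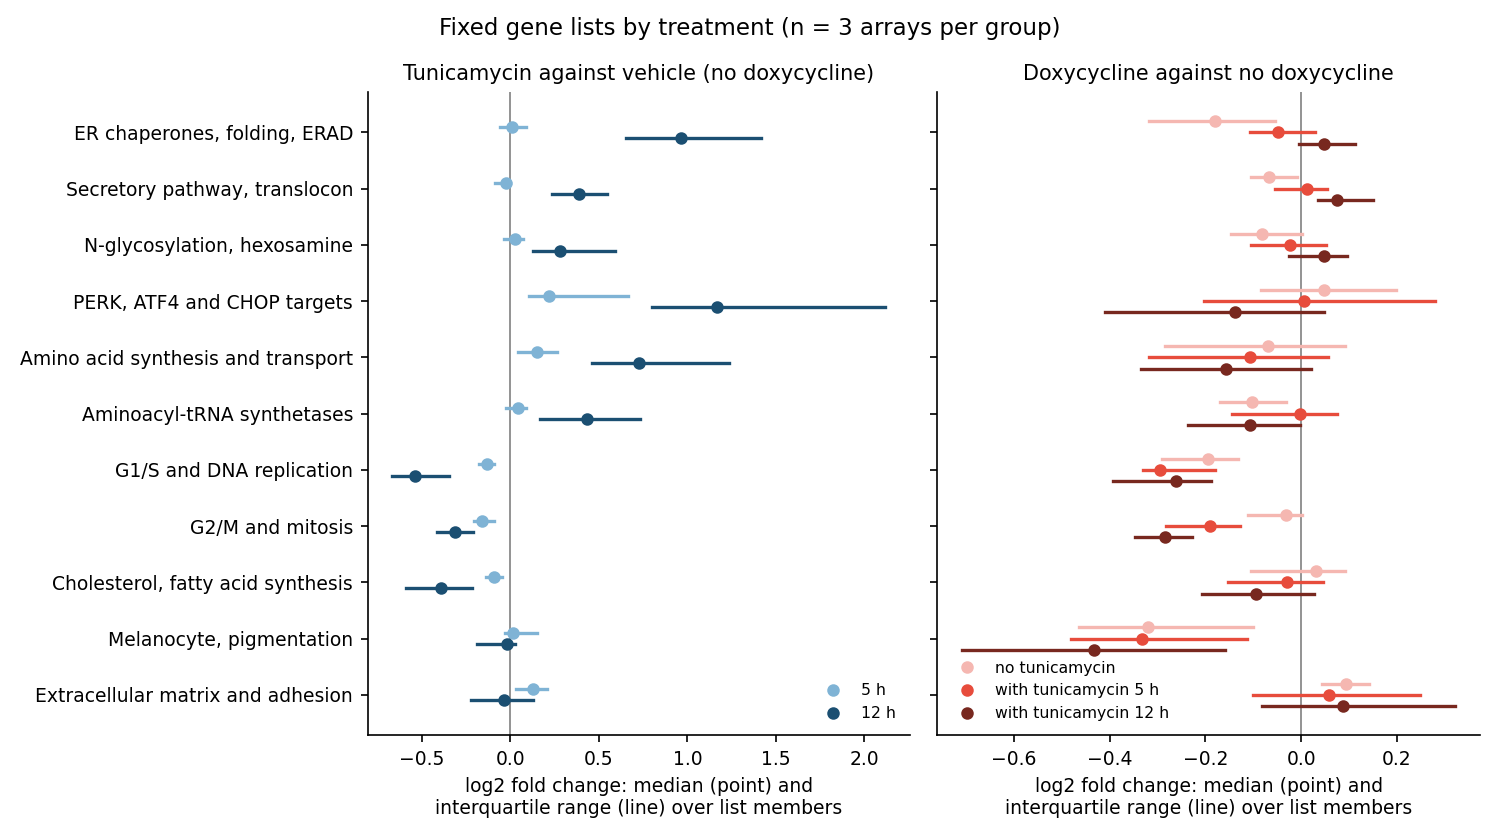
Median log2 fold change (points) and interquartile range (lines) over the members of 11 gene lists, with tunicamycin against vehicle at 5 and 12 h (left) and with doxycycline against no doxycycline at each time (right); 3 arrays per group, and the panels have different scales. ER chaperones had medians of 0.01 at 5 h and 0.96 at 12 h, and pigment genes had medians of -0.32, -0.33 and -0.43 with doxycycline.

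Between 5 and 12 h of tunicamycin the ER folding genes rose and many immediate early genes fell. Of the 29 chaperone and ERAD genes 28 were higher at 12 h and 0 lower, also adjusted over the list alone (median 0.94, camera adjusted p = 5.08e-44, adjusted p = 0.000674 with an estimated correlation). Ero1b changed by 2.95, Dnajb9 by 1.82, Wfs1 by 1.74 and Creld2 by 1.56. Of 27 immediate early and MAPK feedback genes 14 fell and 2 rose (15 and 3 adjusted over the list alone; median -0.27, camera adjusted p = 7.15e-05, adjusted p = 0.0629 with an estimated correlation). Etv5 (-1.41), Dusp4 (-1.02), Spry4 (-0.94) and Maff (-0.78, to a level of 5.96) were among these. Matrix and adhesion genes fell in 11 of 30 cases and rose in 2 (13 and 2 adjusted over the list alone; median -0.14, camera adjusted p = 0.00255, adjusted p = 0.205 with an estimated correlation), where Ccn2 (-1.40), Thbs1 (-1.20) and Itga5 (-0.60) fell and the laminin Lama4 rose by 0.71.

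Other large rises after 5 h were in Nucb2 (2.62), the Notch effector Hey2 (2.48), Casp4 (2.39), Nupr1 (2.33) and Dthd1 (2.25). At 5 h Hey2 stood at 5.73 and Dthd1 at 5.03, below the 6.07 under which 95% of silent receptor genes lay. Rapgef3 (-1.58), Id1 (-1.30), the prokineticin receptor Prokr1 (-1.27) and Kank4 (-1.27) fell. Ddit3 (1.71), Trib3 (1.75), Atf3 (1.04), Atf4 (0.70), Hspa5 (0.70), Xbp1 (0.86) and Cebpb (0.78) were higher at 12 h, each with an adjusted p no larger than 9.43e-08. In all 4983 genes changed, 2264 up and 2719 down; with array medians set equal the directions were 2606 up and 1868 down. Of 16 lists past the camera threshold 8 passed with an estimated correlation.

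Doxycycline on top of 5 h of tunicamycin lowered pigment, replication and mitotic genes. Cebpb was higher by 1.81 ± 0.071 (adjusted p = 2.83e-11). Of 24 melanocyte genes 16 fell and 0 rose (18 and 0 adjusted over the list alone; median -0.33, camera adjusted p = 9.89e-17, adjusted p = 0.0137 with an estimated correlation). Mc1r changed by -0.86, Mitf by -0.73, Gpr143 by -0.68 and Rab27a by -0.64. G1/S genes fell in 22 of 30 cases (26 adjusted over the list alone; median -0.30, camera adjusted p = 1.64e-17, adjusted p = 0.0596 with an estimated correlation). Mcm3 (-0.45), Cdc6 (-0.44), Mcm10 (-0.39) and Uhrf1 (-0.39) were among these. Mitotic genes fell in 22 of 33 cases (28 adjusted over the list alone; median -0.19, camera adjusted p = 4.76e-16, adjusted p = 0.0596 with an estimated correlation). Kif20b (-0.36), Espl1 (-0.36), Ccnf (-0.35) and Birc5 (-0.34) were among these, Ccnf losing its call with only the compared groups (adjusted p = 0.0576).

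Matrix and adhesion genes rose in 12 of 30 cases and fell in 4 (13 and 5 adjusted over the list alone; median 0.06, camera adjusted p = 0.00255, adjusted p = 0.31 with an estimated correlation). Itga5 changed by 1.25, Thbs1 by 1.23, Ccn2 by 0.93 and Itga4 by -0.77. The PERK, ATF4 and CHOP targets split, 7 of 21 up and 5 down (8 and 7 adjusted over the list alone; camera adjusted p = 0.701): apart from Cebpb, Atf5 rose by 0.48 and Atf4 by 0.28 (not passing with only the compared groups, adjusted p = 0.0647), while Nupr1 (-0.91), Ndrg1 (-0.58) and Atf3 (-0.46) fell. Dnajb9 stood 0.24 higher (adjusted p = 0.0555; 0.0202 to 0.0496 in 3 alternatives, 0.0496 with the experiments as blocks), Ddit3 at -0.20 (adjusted p = 0.144; 0.0101 with array weights), Trib3 at -0.24 (adjusted p = 0.111; 0.00442 to 0.0451 in 3 alternatives), Hspa5 at -0.05 (adjusted p = 0.696) and Xbp1 at -0.0038 (adjusted p = 0.988). The largest rises were in Cbr2 (2.04), Fstl1 (1.89), the smooth muscle actin Actg2 (1.67), Jam2 (1.54) and the cytokine receptor Lifr (1.42), and the largest falls in Syt4 (-1.44), Nr4a3 (-1.41), Hpgds (-1.40), Prickle1 (-1.31), Dusp4 (-1.10) and Bace2 (-1.09). In all 2386 genes changed, 1348 up and 1038 down, 38 of them by at least 2-fold; the directions were 1773 up and 1832 down with array weights and 1130 and 1186 without the 2 doubted arrays. Of 5 lists past the camera threshold 1, the melanocyte list, passed with an estimated correlation.

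Doxycycline on top of 12 h of tunicamycin lowered mitotic and pigment genes, and the integrin Itga5 was among its largest rises. Of 33 mitotic genes 31 fell and 0 rose (33 and 0 adjusted over the list alone; median -0.28, camera adjusted p = 7.7e-25, adjusted p = 0.0114 with an estimated correlation). Espl1 changed by -0.50, Ccnf by -0.43, Cdc25b by -0.39 and Ttk by -0.38. Of 24 melanocyte genes 18 fell and 0 rose (19 and 0 adjusted over the list alone; median -0.43, camera adjusted p = 1.55e-20, adjusted p = 0.00573 with an estimated correlation). Mc1r changed by -1.24, Rab27a by -1.10, the melanosome adaptor Mlph by -0.92 and Gpr143 by -0.90. Integrin Itga5 rose by 2.72 ± 0.108 (adjusted p = 9.2e-12), a 6.58-fold difference, and the vitamin D receptor Vdr by 2.00 ± 0.083. The haem oxygenase Hmox1 fell by 1.69 ± 0.073 (adjusted p = 2.44e-11).

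G1/S genes fell in 22 of 30 cases (23 adjusted over the list alone; median -0.26, camera adjusted p = 1e-14, adjusted p = 0.108 with an estimated correlation). Mcm3 (-0.60), Cdt1 (-0.51), Uhrf1 (-0.45) and Prim1 (-0.45) were among these. Matrix and adhesion genes rose in 14 of 30 cases and fell in 5, also adjusted over the list alone (median 0.09, camera adjusted p = 0.00189, adjusted p = 0.332 with an estimated correlation). Thbs1 changed by 1.38, Ccn2 by 0.79 and Itga4 by -0.99. PERK, ATF4 and CHOP targets fell in 10 of 21 cases and rose in 3, also adjusted over the list alone (median -0.14, camera adjusted p = 0.00465, adjusted p = 0.332 with an estimated correlation): Nupr1 (-0.94), Atf3 (-0.87, adjusted p = 3.8e-07), Chac1 (-0.61), Trib3 (-0.41, adjusted p = 0.00368) and Ddit3 (-0.28, adjusted p = 0.0279; 0.0516 without the 2 doubted arrays) fell, and the induced Cebpb rose by 1.22. Amino acid genes fell in 10 of 21 cases and rose in 2, also adjusted over the list alone (median -0.16, camera adjusted p = 0.000519, adjusted p = 0.373 with an estimated correlation). Slc1a4 changed by -0.96, Slc38a7 by -0.72, Mthfd1l by -0.67 and Cth by 0.43. ER chaperone and ERAD genes rose in 5 of 29 cases and fell in 1, also adjusted over the list alone (median 0.05, camera adjusted p = 0.02, adjusted p = 0.581 with an estimated correlation). That call was lost without experiment 3 (adjusted p = 0.136), without the tunicamycin 12 h array of experiment 2 (0.0972), and without the doxycycline with tunicamycin 12 h array of experiment 1 (0.0519) or 3 (0.083). Wfs1 (0.40), Dnajb9 (0.30, adjusted p = 0.0126), Selenos (0.30) and Dnajb11 (0.26; adjusted p = 0.0572 with only the compared groups) rose, while Hspa5 stood at -0.01 (adjusted p = 0.974) and Xbp1 at -0.07 (adjusted p = 0.575). Secretory pathway genes rose in 7 of 32 cases (9 adjusted over the list alone; median 0.07, camera adjusted p = 0.000141, adjusted p = 0.129 with an estimated correlation). Kdelr3 changed by 0.69, Srp19 by 0.23, Spcs1 by 0.23 and Arfgap3 by 0.22. With only the compared groups Srp19 (adjusted p = 0.05), Spcs1 (0.0547) and Arfgap3 (0.0518) did not pass, nor did Arfgap3 with array medians set equal (0.0882) or without the 2 doubted arrays (0.102).

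Of 22 NRF2 antioxidant genes 6 fell and 2 rose (6 and 3 adjusted over the list alone; median -0.04, camera adjusted p = 0.084; 0.000483 in fry and 0.038 without the 2 doubted arrays), Osgin1 (-0.42), Pgd (-0.39) and Gstp1 (-0.36) with Hmox1. Cholesterol and fatty acid synthesis genes fell in 8 of 24 cases (10 down and 1 up adjusted over the list alone; median -0.09, camera adjusted p = 0.00355, adjusted p = 0.373 with an estimated correlation). Cyp51 (-0.50), Elovl6 (-0.41), Insig1 (-0.34) and Msmo1 (-0.31) were among these. The largest rise of all was in Ogn, a small leucine-rich proteoglycan (3.39 ± 0.103), which reached 8.72 ± 0.183 (SD, n = 3) in this group and lay at 5.38 or lower, in the range of silent receptor genes, in the other 5 groups. Cbr2 (2.27), Fstl1 (2.25) and Jam2 (2.01) again rose, and Dthd1 (-1.85), Syt4 (-1.48), Nat8f5 (-1.43, a member of a multigene family), the phospholipase Pla2g2e (-1.42) and Hpgds (-1.42) fell; Dthd1 and Nat8f5 fell back to that same low range. In all 2936 genes changed, 1386 up and 1550 down, 60 of them by at least 2-fold; with quantile normalization repeated the directions were 1667 up and 1511 down. Of 11 lists past the camera threshold 2, the mitotic and melanocyte lists, passed with an estimated correlation.

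The doxycycline effects at the 3 times were compared on separate arrays. Across genes, which are not independent replicates, the log2 changes at 0 h and with 5 h of tunicamycin had r = 0.671, and 717 genes were higher in both (65.9 if the calls were independent), 599 lower in both (60.4 if independent) and 2 opposite. At all 3 times 546 genes were higher and 459 lower with doxycycline, against 4.58 and 4.70 if the calls were independent. The calls share 1 estimate of each gene's spread, so independence is only a rough reference.

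Under doxycycline, tunicamycin raised PERK targets and some ER genes at 5 h and lowered mitotic genes. Against doxycycline alone, 11 of 29 chaperone and ERAD genes rose and 1 fell (14 and 1 adjusted over the list alone; median 0.10, camera adjusted p = 1.64e-07, adjusted p = 0.132 with an estimated correlation). Herpud1 changed by 1.07, Dnajb9 by 0.86, Xbp1 by 0.52 and Wfs1 by 0.39. Hspa5 stood 0.16 higher (adjusted p = 0.039), a call lost with only the compared groups (0.0618), with array medians set equal (0.0848) and without any 1 of the 6 arrays (0.0599 to 0.16). PERK, ATF4 and CHOP targets rose in 11 of 21 cases, also adjusted over the list alone (median 0.25, camera adjusted p = 1.31e-10, adjusted p = 0.0126 with an estimated correlation), with Ddit3 (1.32), Chac1 (1.24), Trib3 (0.83) and Ppp1r15a (0.74); Atf4 rose by 0.29 and Atf3 by 0.25 (adjusted p = 0.0482; 0.0696 with only the compared groups and 0.0636 with array medians set equal), and Cebpb stood at 0.15 (adjusted p = 0.221). Mitotic genes fell in 32 of 33 cases, also adjusted over the list alone (median -0.30, camera adjusted p = 8.27e-32, adjusted p = 0.00834 with an estimated correlation). Cdc25c (-0.52), Cenpf (-0.51), Ccnf (-0.51) and Kif2c (-0.44) were among these. Immediate early genes rose in 17 of 27 cases (18 adjusted over the list alone; median 0.28, camera adjusted p = 8.59e-13, adjusted p = 0.00932 with an estimated correlation). Fos (0.86), Spry4 (0.83), Maff (0.81) and Egr1 (0.73) were among these. Id1 (1.58), Ccn2 (1.55), Id3 (1.49) and Unc5b (1.37) rose most, and Slc39a10 (-1.86), Klf12 (-0.93), Ccng2 (-0.91) and Klhl24 (-0.88) fell most. In all 2413 genes changed, 1304 up and 1109 down, 28 by at least 2-fold.

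At 12 h under doxycycline 28 of 29 chaperone and ERAD genes rose and 0 fell, also adjusted over the list alone (median 1.23, camera adjusted p = 1.19e-42). Ero1b changed by 3.42, Dnajb9 by 2.74, Herpud1 by 2.71 and Wfs1 by 2.19. PERK, ATF4 and CHOP targets rose in 17 of 21 cases (18 adjusted over the list alone; median 0.89, camera adjusted p = 1.62e-21). Ddit3 (2.95), Ppp1r15a (2.79), Nupr1 (2.46) and Trib3 (2.41) were among these. Hspa5 (0.90), Xbp1 (1.31), Atf4 (0.80), Atf3 (0.89) and Cebpb (0.34, adjusted p = 0.000876) rose. Mitotic genes fell in 32 of 33 cases (33 adjusted over the list alone; median -0.54, camera adjusted p = 2.37e-25). Ccnf changed by -1.11, Cenpf by -0.87, Kif2c by -0.82 and Bub1b by -0.80. Melanocyte genes fell in 12 of 24 cases (13 down and 1 up adjusted over the list alone; median -0.17, camera adjusted p = 0.000214, adjusted p = 0.105 with an estimated correlation). Mc1r (-1.03), Met (-0.77), Mlph (-0.59) and Slc45a2 (-0.57) were among these. Ogn (3.62, from the range of silent receptor genes) and Nucb2 (3.00) were also among the largest rises, and Kank4 (-1.39), Klhl30 (-1.35), Nrep (-1.32) and the kinase Map2k6 (-1.25) among the largest falls. In all 5971 genes changed, 2667 up and 3304 down, 215 by at least 2-fold; with array medians set equal the directions were 2957 up and 2680 down. The 12 h responses without and with doxycycline, on separate arrays, had 1868 genes higher in both (316 if the calls were independent), 2427 lower in both (522 if independent) and 30 opposite. These calls too share an estimate of each gene's spread.

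Whether LIP changed the response to tunicamycin was tested as an interaction, the tunicamycin change with doxycycline minus the change without it. At 5 h few single genes passed: Cav1, which encodes caveolin (0.79 ± 0.110, adjusted p = 0.0197), Pwwp3b (0.73 ± 0.111), Osgin2 (0.69 ± 0.112), Socs2 (0.69 ± 0.114, adjusted p = 0.0334; 0.0543 with the experiments as blocks), and, named after their values were seen, Rnd3 and Tagln. Osgin2 and Socs2 lost the call with only the compared groups (0.051 each) and without the 2 doubted arrays (0.0532 each), and with the mean of its probe sets Socs2 stood at 0.40 (0.136). All 6 interactions were positive (70 positive and 49 negative with array weights), 1651 genes had an unadjusted p under 0.05 where 997 would by chance, and leaving out single arrays moved the count between 0 and 15. In camera 10 of 25 lists passed, 9 up and 1 down, and 0 passed with an estimated correlation. The directions were 5 up and 4 down with quantile normalization repeated and 6 and 4 with the receptor-gene covariate. They were 7 and 4 with array weights and 7 and 5 without the 2 doubted arrays. Mitotic genes, the list that shifted down in the main test, had a median interaction of -0.13 (camera adjusted p = 8.62e-12, adjusted p = 0.138 with an estimated correlation). ER chaperone and ERAD genes, among the 9 that shifted up, had a median of 0.10 (camera adjusted p = 2.36e-08, adjusted p = 0.147 with an estimated correlation). Kif2c stood at -0.23 (adjusted p = 0.384), Xbp1 at 0.39 (adjusted p = 0.155; 0.0277 with array weights and 0.041 with a variance trend) and Dnajb9 at 0.44 (adjusted p = 0.221). No member of the mitotic or chaperone list passed over all genes in limma. Adjusted over the list alone, 6 chaperone genes and 0 mitotic genes passed. The remaining fixed stress genes, Cebpb (-0.03), Ddit3 (0.14), Atf4 (-0.08), Atf3 (-0.41), Trib3 (-0.33) and Hspa5 (0.17), had adjusted p between 0.338 and 0.947; with array weights Atf3 passed (0.0285).

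At 12 h the arms of the ER stress response differed in the sign of their interaction with doxycycline. ER chaperone and ERAD genes had a more positive tunicamycin change with doxycycline, by a median of 0.21 (8 of 29 genes positive and 0 negative, 20 and 0 adjusted over the list alone; camera adjusted p = 3.41e-18, adjusted p = 0.0191 with an estimated correlation), including Dnajb9 (0.50 ± 0.111, adjusted p = 0.0229), Creld2 (0.47), Selenos (0.45; adjusted p = 0.0545 without the 2 doubted arrays) and the disulfide isomerase Pdia6 (0.45). PERK, ATF4 and CHOP targets had a less positive change, by a median of -0.21 (5 of 21 negative and 0 positive, 11 and 0 adjusted over the list alone; camera adjusted p = 4.81e-10, adjusted p = 0.0156 with an estimated correlation), including Atf3 (-0.82 ± 0.115, adjusted p = 0.000535), Cdsn (-0.77) and Nupr1 (-0.61). Cebpb, also on that list, had an interaction of -0.62 ± 0.100 (adjusted p = 0.00247), but its probe set also reads the induced LIP: the doxycycline and tunicamycin signals simply added give 11.52 at 12 h, and 11.52 was measured, so no weaker response of the gene is shown. Without Cebpb the median of the other 20 genes was -0.19. For the chaperone list median the difference lay mostly at the start, where doxycycline alone gave -0.18 against 0.05 at 12 h of tunicamycin. Hspa5, above the bound of 12 used in the ceiling check below, was 12.90 in vehicle and 12.69 with doxycycline. It was 13.59 in both groups at 12 h (interaction 0.21, adjusted p = 0.164, or 0.0218 with a variance trend). Dnajb9 and Selenos instead differed more at 12 h. Dnajb9 read 9.95 to 10.13 in vehicle and 9.74 to 9.94 with doxycycline. At 12 h it read 12.21 to 12.30 without and 12.48 to 12.65 with doxycycline. Selenos read 9.5 to 9.7 in vehicle and 9.3 to 9.5 with doxycycline, and at 12 h 10.8 to 10.9 without and 11.1 to 11.2 with it.

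**Figure D3:**
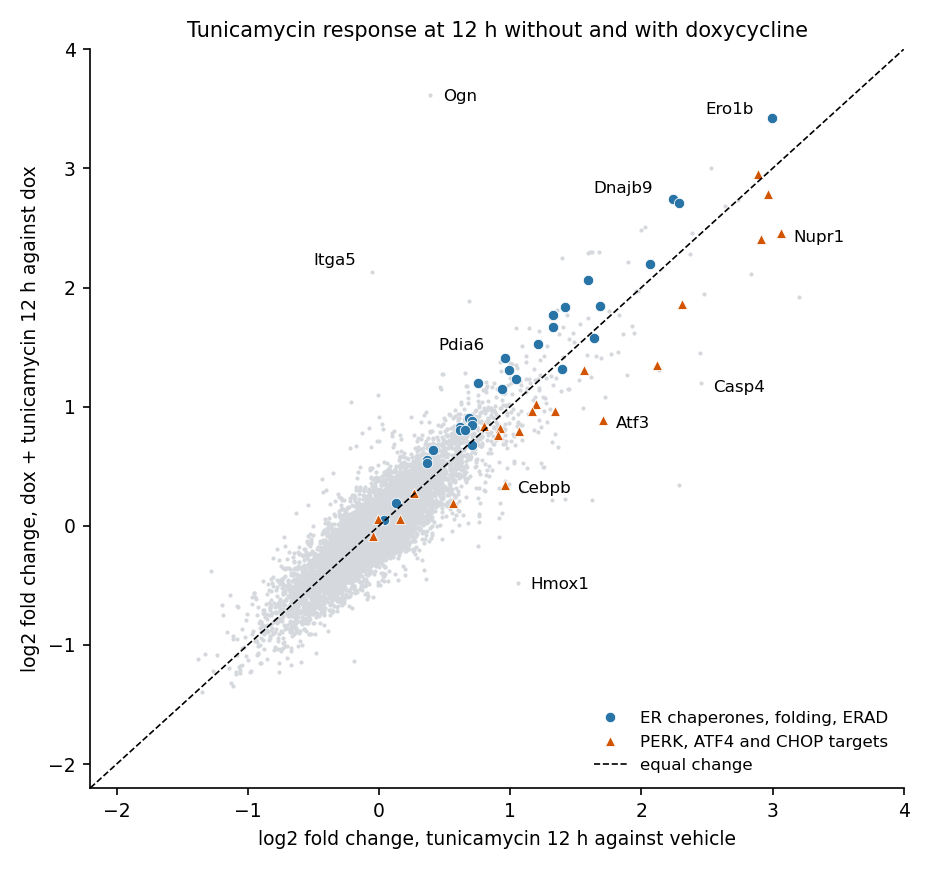
Log2 fold change of each of 19938 genes after 12 h of tunicamycin, without doxycycline (x axis) and with it (y axis, against doxycycline alone); the dashed line marks equal change. Of the ER chaperone and ERAD genes (blue circles) most lie above the line, with a median interaction of 0.21, and of the PERK, ATF4 and CHOP targets (orange triangles) most lie below it, with a median of -0.21.

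Secretory pathway genes shifted with the chaperones (median 0.17; 2 of 32 positive, 10 adjusted over the list alone; camera adjusted p = 1.19e-14, adjusted p = 0.00748 with an estimated correlation). Sec24d had an interaction of 0.48 and Spcs3 of 0.40. For Spcs3 this lay mostly at the start, with arrays at 11.17 to 11.32 in vehicle and 10.85 to 10.91 with doxycycline. At 12 h Spcs3 read 11.57 to 11.64 without and 11.64 to 11.67 with doxycycline. Sec24d differed at both times, at 8.92 to 8.96 and 8.54 to 8.73 at the start. At 12 h it read 10.91 to 11.03 without and 11.13 to 11.18 with doxycycline. N-glycosylation genes shifted the same way (median 0.13; 2 of 31 positive, 9 adjusted over the list alone; camera adjusted p = 1.27e-07, adjusted p = 0.0571 with an estimated correlation). Alg5 had an interaction of 0.46 and Pgm3 of 0.35. The Pgm3 gap was wider at the start (8.75 to 8.84 in vehicle, 8.52 to 8.58 with doxycycline). At 12 h Pgm3 read 9.72 to 9.91 without and 9.87 to 9.96 with doxycycline. The Alg5 gap was wider at 12 h (10.53 to 10.73 without, 10.94 to 11.03 with doxycycline). At the start Alg5 read 9.65 to 9.77 in vehicle and 9.56 to 9.66 with doxycycline. Mitotic genes shifted down (median -0.22; 8 of 33 negative, 26 adjusted over the list alone; camera adjusted p = 4.25e-22, adjusted p = 0.0156 with an estimated correlation). Cdc25c had an interaction of -0.36, Espl1 of -0.35, Kif2c of -0.32 and Plk1 of -0.31, and these 4 genes had adjusted p between 0.0538 and 0.0934 with array medians set equal. Melanocyte genes also shifted down (median -0.10; 4 of 24 negative, 8 adjusted over the list alone; camera adjusted p = 3.69e-05, adjusted p = 0.118 with an estimated correlation). Mlph had an interaction of -0.51, Rab27a of -0.49, Pmel of -0.48 and Sox10 of -0.32; with array medians set equal Rab27a (adjusted p = 0.0847) and Sox10 (0.062) did not pass, nor did Rab27a without the 2 doubted arrays (0.0513).

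The largest interactions were in Ogn (3.23 ± 0.146), Itga5 (2.19 ± 0.153), Vdr (1.25 ± 0.117) and the transcription factor Gata3 (1.20 ± 0.096), and in Dthd1 (-1.94 ± 0.117), Hmox1 (-1.53 ± 0.103), Nat8f5 (-1.41 ± 0.135) and Casp4 (-1.26 ± 0.141). Ogn, Dthd1 and Nat8f5 lay in the range of silent receptor genes in 5 of the 6 groups. Hmox1 stood at 9.46 in vehicle, 9.31 with doxycycline and 10.52 after 12 h of tunicamycin, but at 8.83 after tunicamycin with doxycycline. Ddit3 (0.06, adjusted p = 0.89), Atf4 (-0.27, adjusted p = 0.131), Trib3 (-0.50, adjusted p = 0.0533) and Xbp1 (0.32, adjusted p = 0.074) did not pass, though alternatives gave calls in the same direction for Trib3 in 6 cases (0.0116 to 0.0386), Xbp1 in 4 (0.0135 to 0.0474) and Atf4 in 2 (0.0252 and 0.0407). Of 367 genes in all, 198 were positive and 169 negative; these were 230 and 87 with array medians set equal, 230 and 266 with the receptor-gene factor as a covariate, and 158 and 170 without the 2 doubted arrays. Of 10 lists past the camera threshold 4 passed with an estimated correlation, namely chaperones, secretory pathway, PERK targets and mitosis.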

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

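The comparison for a general weakening and the removal of the common doxycycline effect were chosen after the results they measure were seen. Tests with the receptor-gene factor, the ceiling and the matched random lists were chosen after the patterns were seen but before their own results.

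At 12 h the doxycycline by tunicamycin interaction differed from 0 with opposite signs for ER chaperone and ERAD genes (median 0.211) and for PERK, ATF4 and CHOP targets (median -0.207, or -0.191 without Cebpb). A ceiling on bright probe sets is argued against for the 13 chaperone genes with all group means under 12. Their median interaction was 0.187 ± 0.052 (SE). The SEs in this paragraph come from resampling list members, which are not independent, so they do not measure the spread between experiments. An array quality factor read from the receptor genes is argued against too, since with it as a covariate the lists' medians differed by 0.414, against 0.418 without it. The covariate takes its slope from differences between arrays of the same group. It therefore cannot speak to a quality difference that goes with the groups. A tunicamycin response weakened alike in all genes would make the chaperone median negative, and it was 0.211 ± 0.038 (SE). That median is part of the pattern in question and reflects mostly a lower start. It is therefore no separate test of a weakening. A hypothesis that stays open, and was not tested, is that LIP may act differently on the arms of the response. For the chaperones as a list, though not for Dnajb9 and Selenos, this may lie mostly in lower transcripts before tunicamycin. That lower start (median -0.179) lost its call in camera with an estimated correlation (adjusted p = 0.162). An effect of doxycycline itself was not analysed here.

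Pigment cell genes were lower with doxycycline alone, by a median of -0.319. A shift that depends on brightness is argued against: the list median lay at percentile 0 of 10000 random lists matched on mean expression, the lowest of which was -0.0936. The array quality factor is argued against, with the same limit to quality that varies within groups, as the median was -0.307 with it as a covariate. Loss of pigment cell transcripts through LIP may be proposed as a hypothesis, which these checks do not test. An effect of doxycycline without the construct was not analysed here.

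The other differences between groups, each from the test of the interaction, were these. At 12 h 367 genes passed, among them Ogn (3.23), Itga5 (2.19), Vdr (1.25), Gata3 (1.20), Dnajb9 (0.50), Dthd1 (-1.94), Hmox1 (-1.53), Nat8f5 (-1.41), Casp4 (-1.26) and Atf3 (-0.82). Cebpb also passed (-0.62), but the doxycycline and tunicamycin signals simply added give the level measured (11.52), so this shows no difference in response. Of 10 lists past the camera threshold at 12 h, 4 up and 6 down, only those described above are given. Besides those weighed, they had medians of -0.218 (mitosis), 0.165 (secretory pathway), 0.129 (N-glycosylation) and -0.103 (melanocyte lineage). The last 2 were lost with an estimated correlation (adjusted p = 0.0571 and 0.118). At 5 h 6 genes passed, among them Cav1 (0.79), Pwwp3b (0.73), Osgin2 (0.69) and Socs2 (0.69). In camera 10 of 25 lists passed at 5 h, 9 up and 1 down, a split that changed with the processing as given above. With an estimated correlation 0 passed. Of the 10 lists, mitosis and chaperones had medians of -0.126 and 0.104 (adjusted p = 0.138 and 0.147 with an estimated correlation). Socs2 had an interaction of 0.40 with the mean of its probe sets (adjusted p = 0.136).

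Signal also changed in data that no comparison used: of 13768 probe sets without a single gene symbol, 1576 passed for tunicamycin at 12 h against vehicle and 179 for doxycycline at 12 h of tunicamycin. Chosen after its values were seen, probe set 10348902, shared by several genes and so not named, had the largest rise with doxycycline at 0 h of any probe set, 3.35 ± 0.135 (SE, limma adjusted p = 3.33e-09); whether it reads sequence of the construct or vector was not determined.

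Other splits of the same arrays were counted for each comparison. The 6 arrays of a pair of groups make 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each of these 8 comparisons: 2135 (doxycycline at 0 h), 1798 (tunicamycin at 5 h), 5516 (tunicamycin at 12 h), 4983 (12 against 5 h), 2413 and 5971 (tunicamycin under doxycycline at 5 and 12 h), each with a highest other count of 0, and 2386 and 2936 (doxycycline at 5 and 12 h of tunicamycin), with highest other counts of 2 and 1. Of the 10 splits 4 part all 3 pairs of experiments, and the highest other count among these was 0. For the interactions chance was not excluded by this count: 11 of 100 splits drawn gave at least 6 genes at 5 h (highest other 2242) and 7 of 100 gave at least 367 at 12 h (highest other 4030). The other 10 and 6 of these splits kept or reversed the doxycycline labels at one of the times, so their counts carry the doxycycline effect, a structure of the samples. With the doxycycline difference common to both times removed, 1 of 100 splits, the real one, gave as many genes at each time (highest others 2 and 1). This removal used the real labels. It leaves the real counts as they were and takes doxycycline signal out of the other splits, so it cannot exclude chance.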

How the results depend on the processing

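The receptor-gene covariate and the fit without the doubted arrays were chosen after the data were seen; all other alternatives were planned.

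Signal over background limits the dim genes, since 70.6% of genes lay above the 95th percentile of the receptor genes. Over the alternatives that keep all experiments, 594 of 624 values for described lists other than the PERK, ATF4 and CHOP targets kept their direction and side of the threshold. Of the rest 25 lost and 4 gained the call, and 1 reversed. All 25 losses came with an estimated inter-gene correlation, so the share kept over all alternatives does not measure how the lists hold under that setting. The reversal was in apoptosis regulators at 12 h of tunicamycin, with a median of 0.0186, lower in camera and higher in fry (adjusted p = 0.0437). For named genes, with values of the PERK, ATF4 and CHOP list counted among them, 3679 of 3738 kept both, 31 lost and 28 gained the call, and 0 reversed. With single arrays or experiments left out, 3370 of 3639 values counted in this way kept both, 263 lost and 6 gained the call. Named genes whose call ended without a single array, with the number of such arrays and the highest adjusted p, were for doxycycline at 0 h Cxcl10 (5, 0.109), Ddit3 (3, 0.0692), Gbp3 (1, 0.0628), Mcm3 (1, 0.0614); for tunicamycin at 5 h Cebpd (6, 0.116), Cebpg (4, 0.137), Fos (4, 0.074). Others were for doxycycline at 12 h Arfgap3 (5, 0.174), Ddit3 (5, 0.102), Dnajb11 (1, 0.0624), Dnajb9 (2, 0.069), Selenos (2, 0.0554), Spcs1 (1, 0.0591), Srp19 (3, 0.0665); for tunicamycin at 5 h under doxycycline Atf3 (5, 0.264), Hspa5 (6, 0.16). In the interactions they were for 5 h interaction Cav1 (7, 0.0727), Osgin2 (11, 0.123), Pwwp3b (9, 0.0909), Socs2 (10, 0.144); for 12 h interaction Cdc25c (5, 0.0627), Dnajb9 (6, 0.0742), Espl1 (4, 0.0601), Kif2c (3, 0.0611), Pgm3 (9, 0.0889), Plk1 (2, 0.0622), Rab27a (9, 0.14), Selenos (9, 0.137), Sox10 (6, 0.0607). The cholesterol list with doxycycline at 12 h lost its call without 1 array (adjusted p = 0.0629). The cause of a moved count was not tested except where fewer samples or a stricter threshold gives it.

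With the experiments as blocks the counts were 2256 and 1879 (doxycycline at 0 h; tunicamycin at 5 h), 5630 and 5105 (tunicamycin at 12 h; 12 against 5 h), 2438 and 3013 (doxycycline at 5 and 12 h of tunicamycin), 2491 and 6055 (tunicamycin under doxycycline), and 8 and 401 (interactions), and this pairing changed no call of a described list or named gene except those of Dnajb9 and Socs2 given with their comparisons. With array weights 3631 genes changed with doxycycline at 0 h, 4381 with tunicamycin at 5 h and 3605 with doxycycline at 5 h (8 lists), and 119 and 777 (interactions), the 119 in 70 up and 49 down. At least 2-fold were 16, 17, 187, 170, 38, 60, 28, 215, 0 and 13 (doxycycline at 0 h; tunicamycin at 5 h, at 12 h and 12 against 5 h; doxycycline at 5 and 12 h; tunicamycin under doxycycline at 5 and 12 h; interactions in limma). With only the compared groups fitted the counts were 1054 (tunicamycin at 5 h), 1413 (doxycycline at 5 h) and 2 (5 h interaction). The interaction counts were 15 at 5 h with array medians equalized, and 27 and 567 with a variance trend. Without the 2 doubted arrays tunicamycin at 5 h changed 820 genes up and 604 down. The larger direction also turned with quantile normalization repeated for doxycycline at 0 h (1245 up, 1083 down) and 12 h (1667, 1511) and tunicamycin at 5 h (987, 920), with array weights for doxycycline at 5 h (1773, 1832) and tunicamycin at 5 h (2247, 2134), with the receptor-gene covariate for tunicamycin at 5 h (966, 814), and without the doubted arrays for doxycycline at 5 h (1130, 1186).

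Lists past the threshold with an estimated correlation were 1 (doxycycline at 0 h), 3 (tunicamycin at 5 h), 8 (12 against 5 h), 1 and 2 (doxycycline at 5 and 12 h), 4 (tunicamycin under doxycycline at 5 h), and 0 and 4 (interactions); with fry they were 8 and 17 (doxycycline at 5 and 12 h) and 4 (5 h interaction).

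With each array and each experiment left out in turn the counts ranged over 652 to 1639 (doxycycline at 0 h), 419 to 1728 (tunicamycin at 5 h), 3617 to 5359 (at 12 h), 3283 to 4730 (12 against 5 h), 1012 to 2243 and 1454 to 2900 (doxycycline at 5 and 12 h), 941 to 2015 and 4078 to 5862 (tunicamycin under doxycycline), 0 to 15 and 39 to 472 (interactions). Single arrays that moved a count by over 1.5 times were vehicle of experiment 1 (1379 for doxycycline at 0 h, 1176 for tunicamycin at 5 h, 231 for the 12 h interaction) and of experiment 3 (1120 for tunicamycin at 5 h, 234 for the 12 h interaction). For the 12 h interaction the count was also 214 and 238 without doxycycline of experiments 1 and 3, 239 without tunicamycin 12 h of experiment 3, and 224 without doxycycline with tunicamycin 12 h of experiment 3. The 5 h interaction had 0 genes without any 1 vehicle array, without tunicamycin 5 h of experiment 2 or 3, or without doxycycline with tunicamycin 5 h of experiment 1 or 2, 2 without doxycycline of experiment 1 or 3, and 15 without tunicamycin 5 h of experiment 1.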

Other observations

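The members of the SMAD, zinc and SRF and YAP lists below were written, and their tests chosen, after the leading genes had been seen. The members not seen beforehand were tested apart from those. The SRF and YAP targets counted as not seen include Ccn1, although it is named above with the matrix genes at 5 h of tunicamycin. That set is therefore not wholly separate.

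At 5 h of tunicamycin targets of BMP and TGF-beta signalling through SMAD proteins stood out beside Id1 (1.64) and Id3 (1.75). The inhibitory SMADs Smad6 (1.13) and Smad7 (0.87), Pmepa1 (1.08) and the netrin receptor Unc5b (1.05) rose in limma. Of 20 further SMAD targets 6 rose and 0 fell, among them Atoh8 (1.00), Id2 (0.60), Skil (0.55) and the BMP antagonist Nog (0.43). Of the zinc-responsive genes seen beforehand the metallothionein Mt2 (1.09) and the exporter Slc30a1 (1.36) rose and the importer Slc39a10 (-1.98) fell; of 6 further ones Mt1 (0.41) passed and Mt3, Slc30a2, Slc30a4, Slc30a10 and Mtf1 did not (median 0.09), and they were not tested as a list.

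Many SRF and YAP targets were higher with doxycycline at each of the 3 times. At 0 h, though, Cav1 was lower (-0.39) and Tagln did not pass (0.05). Acta1, Acta2, Cnn1 and Ankrd1 did not pass at any of the 3 times (0.14 to 0.15 at 12 h of tunicamycin). At 12 h of tunicamycin vinculin Vcl (0.84), the receptor kinase Axl (0.81), calponin Cnn2 (0.74), Crim1 (0.72), the actinin Actn1 (0.64), Tpm4 (0.54) and the transcription factor Srf (0.47) passed in limma, with Actg2 (1.59), Cav1 (0.45) and Tagln (0.44), while Ptpn14 (-0.35) and Filip1l (-0.28) were lower with doxycycline. Tunicamycin alone at 12 h raised 3 of the 26 targets not seen beforehand (median of the 26 -0.03), Ccn1 (0.35), Zyx (0.28) and Axl (0.20), and lowered 7, Vcl (-0.57), Actn1 (-0.42), Cnn2 (-0.38), Tpm4 (-0.31), Srf (-0.23), Ptpn14 (-0.22) and Myl9 (-0.21). The 12 h interaction passed for Vcl (0.37), Tpm4 (0.31) and Actn1 (0.31), 3 of the 26 not seen beforehand, and for Itga5 (2.19), Cav1 (0.85), Thbs1 (0.58) and Tagln (0.39), 4 of the 6 seen. Of 26 SRF and YAP targets not seen beforehand 13 rose and 2 fell with doxycycline at 0 h (median 0.22), 16 and 1 at 5 h (median 0.31), and 14 and 2 at 12 h (median 0.24).

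A wider SMAD target response at 5 h was tested on the 20 members not seen beforehand, whose median was 0.142 (camera adjusted p = 2.53e-06, adjusted p = 0.00371 with an estimated correlation), and the prediction was met. An array quality factor that varies within groups is argued against, since the 6 targets seen beforehand had a median of 1.1 with it as a covariate and 1.11 without. Handling or time in culture cannot be told apart from tunicamycin, because vehicle arrays at 5 and 12 h were not used here; the median of those 6 was 0.445 at 12 h, as a passing stimulus could also give. A wider SRF and YAP target response with doxycycline, larger for some members after 12 h of tunicamycin, may be proposed on the same footing; as a list the 26 members not seen beforehand were tested only at 12 h (median 0.24, camera adjusted p = 5.48e-11, adjusted p = 0.00289 with an estimated correlation).

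Over the 8 comparisons of a pair of groups, 0 to 3 of 20 markers of other cell types passed (smallest camera adjusted p = 0.623) and 0 to 1 of 10 reference genes (smallest 0.337). C/EBP-linked inflammatory and acute phase genes passed in 1 to 6 of 27 cases (smallest camera adjusted p = 0.0834). At 12 h of tunicamycin hypoxia and glycolysis genes fell in 13 of 25 cases and rose in 6 (15 and 6 adjusted over the list alone; camera adjusted p = 0.0425, adjusted p = 0.465 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 9 of 30 cases, also adjusted over the list alone (camera adjusted p = 0.00861, adjusted p = 0.404 with an estimated correlation), and mitochondrial chaperones and proteases rose in 6 of 14, also adjusted over the list alone (camera adjusted p = 0.00377, adjusted p = 0.171 with an estimated correlation). Of 19 p53 targets 6 fell at 5 h of tunicamycin and 0 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.00804, adjusted p = 0.0809 with an estimated correlation).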
